A study of Homo sapiens with 6 samples.

How the data were processed

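PolyA RNA was measured by RNA sequencing in 6 libraries of HEY, an established human ovarian cancer cell line. Per the labels, 3 libraries came from cells overexpressing miR-200a, a microRNA of the miR-200 family, and 3 from cells with the empty vector. Per the labels' protocols, the cells were grown in RPMI-1640 medium with fetal bovine serum, and libraries were made with a SMARTer mRNA-Seq kit. The labels give 48, 49 and 50 h of incubation for miR-200a libraries 1 to 3 and 51, 52 and 53 h for vector libraries 1 to 3, so the hours lie apart between the groups and were not used as a covariate. They go up by 1 h from sample to sample in the order of the labels, and whether they are real times is not known. All 6 libraries carry batch number 1. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

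The deposited table holds FPKM values (fragments per kilobase of gene, scaled to the size of the library), made by the authors, for 58735 genes and 6 value columns, 1 per library. The aligner, the counting tool and whether counting used strand are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. All 58735 gene identifiers, starts, ends and gene lengths in the deposited table equalled those of the human GENCODE 29 annotation, so coordinates are given on GRCh38. Multiplying each deposited FPKM value by the deposited gene length and by 1 scaling total per library gave whole reads for 100% of the nonzero values, within 0.001 of a read. The authors' scaling totals equalled library totals scaled by median-of-ratios size factors over the 18607 genes above 0 in all libraries. Recovered reads came to 18007328, 15849592 and 18537449 in miR-200a libraries 1 to 3 and to 21003858, 17928330 and 16107478 in vector libraries 1 to 3. A single read in a 1-kb gene was worth 0.0475 to 0.0626 FPKM. Intervals and floors derived from reads cover counting error only. The chi-square per degree of freedom between libraries, over genes with at least 20 summed reads, was 2.08 for miR-200a 1 and 3 and 4.61 to 32.5 for the other pairs. No pair agreed within sampling noise, so no library was treated as a copy of another, which does not show that they came from separate cultures. miR-200a 2 was closer to vector 2 (6.74) than to miR-200a 1 (19.6) or miR-200a 3 (21.9).

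The choices of test, filter, named genes, gene lists and most of the other settings were made before the data were examined. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), with the group as the only term. The test was two-sided and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes given as log2 are differences on the log2(FPKM + 1) scale, which understates changes of low genes, and folds without log2 are ratios of mean FPKM. For WNT5A, IL6 and VTCN1, the genes behind the names in the study's title, an exact two-sided permutation test over the 10 splits of the libraries was run, whose smallest possible p is 0.1.

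The genes to be named were WNT5A, IL6, VTCN1, ZEB1, ZEB2, CDH1, VIM and CTNNB1 always. To these the rule added the 12 largest increases and the 12 largest decreases among genes past the threshold with a usual symbol, a mean of at least 2 FPKM in the higher group and no overlap between the groups. It also took up to 4 members per list with the smallest adjusted p. Some genes that the rule takes are not reported here. IL1A, CXCL2, CXCL3, BIRC3, ICAM1, EPCAM, CLDN7, CD274, GAPDH, ID1 and SMAD3 lie outside the rule and were chosen after their values were seen. The genes that mark the ends of genome stretches were chosen in the same way. The 23 gene lists were reported miR-200a/141 targets, epithelial genes, mesenchymal genes, Wnt ligands and receptors, Wnt/beta-catenin targets, the IL-6/STAT3 pathway, NF-kB cytokines and targets, the B7 family and immune ligands, HLA class I presentation, proteases, integrins and invasion, TGF-beta response, YAP/TEAD targets, interferon response, proliferation, p53 targets, hypoxia and glycolysis, the unfolded protein and integrated stress responses, NRF2 targets, cholesterol synthesis, ovarian lineage, markers of other cell types, mitochondrial transcripts and reference genes. Each list with at least 5 tested members was compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation, adjusted over the lists. limma's fry was run as well.

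The longest annotated 3' UTR of each gene (10542 genes) was scanned for CAGTGTT, the 7-mer that pairs with positions 2 to 8 of mature miR-200a-3p. The 8-mer CAGTGTTA, the site of miR-200b and miR-200c, CAGTATT, and all 420 orderings of the bases of CAGTGTT served for comparison. Shares of called genes with a site were compared by Fisher's exact test.

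The other settings fixed at that time were other pseudocounts, filters, scalings and spread models, protein-coding genes alone, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a limma voom fit on the recovered reads (at least 10 reads in at least 3 libraries), a correction of each library for GC content and gene length by loess (span 0.3), the same with the replicate block, and a fit without miR-200a libraries 1 and 3. Also chosen after seeing the data was a test for neighbouring genes. It took 9865 genes with a mean of at least 2 FPKM in genome order, in 384 blocks of 25 genes, and used as limit the largest block median in the other 9 splits of the libraries. Genes left over at the end of a chromosome, too few for a block, were in no block. Stretches were runs of at least 2 neighbouring blocks beyond the limit in the same direction.

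The fit was tested on simulated reads drawn from the means of these libraries, with 200 genes changed. Every simulated gene had the same spread beyond counting error (dispersion 0.005871) and genes varied independently. Apart from the GC trend, no structure between libraries was put in, so the shares found may be too high for the real genes. Without a GC trend, 12236 genes were tested, and 62.7% of the genes changed by 1.5-fold, 88.1% of those changed by 2-fold and 97.0% of those changed by 4-fold were found, with 12 false calls among 177. With a GC trend like that of these libraries, 12255 genes were tested and the 1.5-fold changes were found in 47.8% of cases before the correction and in 64.2% after it, with 19 false calls among 174 and 18 among 186. In that simulation, with no effect of seed sites put in, genes with a site were shifted by -0.039 before and -0.0004 after the correction. In the test for neighbouring genes, 75 of 9865 genes shifted by 0.2 were found in 3 of 3 blocks, with 0 false blocks. The shift was added to a split that had itself helped to set the limit, so a false block was not possible. The shifted genes filled whole blocks, so the power for stretches that cross block borders was not measured. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.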

Results

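RNA sequencing was carried out on HEY cells, an established human ovarian cancer line, with or without overexpression of miR-200a. The title of the series names an axis of Wnt5a, IL-6 and B7-H4 in metastasis, and the single comparison of the design was miR-200a against the empty vector, with 3 libraries each. The libraries held 15849592 to 21003858 reads on genes. Between 12130 and 12297 genes reached 1 FPKM per library. Mitochondrial transcripts took 3.23 to 3.85% of the reads and the 10 most abundant genes 5.40 to 5.96%, without a separation of the groups.

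The overexpressed microRNA itself was seen through its precursor gene. MIR200A (ENSG00000207607, chromosome 1, 1167863 to 1167952, GRCh38) had 5, 4 and 11 reads in miR-200a libraries 1 to 3 and 0 reads in each vector library. The 20 reads of the miR-200a group had a 95% Poisson interval of 12.2 to 30.9. Taken as 20 reads, the level was 6.95-fold higher than a floor of 3 reads over the whole vector group. This fold leaves out the counting error of the 20 reads, so it is not a lower limit. The limma adjusted p was 0.0205, and 0.118 without vector 3, and the call was also lost without miR-200a 1, vector 1 or vector 2. The neighbouring and related loci MIR200B, MIR429, MIR200C, MIR141 and MIR200CHG were listed at 0 in all libraries. Mature microRNAs are not captured by polyA libraries, so the level of mature miR-200a was not measured.

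Cells overexpressing miR-200a had higher levels of PAEP, KISS1, C6orf141 and UCA1 than vector cells. PAEP, which encodes the secreted glycoprotein glycodelin (ENSG00000122133, chromosome 9, 135561756 to 135566955), stood at 4.69 ± 0.134 FPKM against 0.297 ± 0.0862 (SD, n = 3 each), a 15.8-fold difference (log2 change 2.14, SE 0.092, limma adjusted p = 0.000315). KISS1, the gene of the secreted peptide kisspeptin, first described as a metastasis suppressor (ENSG00000170498, chromosome 1, 204190341 to 204196486), reached 52.7 ± 1.35 against 13.4 ± 4.18 FPKM, 3.94-fold higher (limma adjusted p = 0.0205, 0.0996 without miR-200a 1, and also lost without miR-200a 3, vector 2 or vector 3). The long noncoding RNA UCA1 (ENSG00000214049, chromosome 19, 15828206 to 15836326) was 3.83-fold higher, at 8.43 ± 0.316 against 2.20 ± 0.17 FPKM (limma adjusted p = 0.000338). C6orf141 was 6.02-fold higher and the noncoding RNA XIST 5.68-fold higher.

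Other large increases were found for PDGFB, HSD11B1 and WNT7A. The growth factor subunit PDGFB was 2.34-fold higher (16.9 ± 3.35 against 7.20 ± 0.20 FPKM, n = 3 each, limma adjusted p = 0.030). HSD11B1, which regenerates active cortisol, was 2.30-fold higher (13.0 ± 1.10 against 5.67 ± 0.697 FPKM, limma adjusted p = 0.0151). WNT7A, a Wnt ligand (ENSG00000154764), was 2.09-fold higher (4.63 ± 0.397 against 2.21 ± 0.210 FPKM, limma adjusted p = 0.0205). The cell-cycle regulator RGCC stood at 12.2 against 4.55 FPKM, the caveolar protein gene CAVIN2 at 4.38 against 1.67 and AFAP1L2 at 2.57 against 1.01. The matrix gene FBLN1 stood at 3.26 against 1.37 FPKM, and it lies in a stretch of chromosome 22 where most genes were slightly higher. With 1 library left out, the highest limma adjusted p was 0.141 for PDGFB, 0.096 for HSD11B1 and 0.118 for WNT7A. It was 0.131 for RGCC, 0.0532 for CAVIN2, 0.15 for AFAP1L2 and 0.194 for FBLN1.

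COLEC10 and a set of inflammatory cytokines were lower with miR-200a. COLEC10, which encodes a secreted collectin of the lectin complement pathway (ENSG00000184374, chromosome 8, 118995452 to 119106582), fell from 37.4 ± 2.73 to 5.69 ± 0.956 FPKM, 6.58-fold (SD, n = 3 each; log2 change -2.53, SE 0.115, limma adjusted p = 0.000315). CXCL8, the gene of the neutrophil chemokine interleukin-8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), fell 2.84-fold, from 14.0 ± 1.71 to 4.94 ± 0.445 FPKM (limma adjusted p = 0.00637). CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242) fell 2.01-fold, from 30.4 ± 1.74 to 15.1 ± 1.11 FPKM (limma adjusted p = 0.00942). IL1B, the gene of interleukin-1 beta (ENSG00000125538, chromosome 2, 112829751 to 112836903), fell 1.77-fold, from 69.8 ± 4.78 to 39.4 ± 1.01 FPKM (limma adjusted p = 0.0151). With 1 library left out, the adjusted p was at most 0.0484 for CXCL8, 0.0802 for CXCL1 (without vector 3) and 0.0996 for IL1B (without miR-200a 1). The CXCL1 call was lost without miR-200a 3, vector 2 or vector 3, and the IL1B call without any library except miR-200a 2.

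Further genes that fell included IGFN1, from 2.06 to 0.540 FPKM, a 3.81-fold difference. The hyaluronan synthase gene HAS2 stood at 3.12 against 5.97 FPKM, the cholesterol exporter gene ABCA1 at 4.97 against 9.08, and the actin-binding scaffold gene MTSS1 at 11.8 against 20.02. The transcription factor gene TFAP2C stood at 6.51 against 11.3 FPKM, and it lies in a stretch of chromosome 20 where most genes were slightly lower. SYT11 and the metalloproteinase gene ADAMTS6 also fell, though the SYT11 call was lost with the replicate block (limma adjusted p = 0.06). With 1 library left out, the highest limma adjusted p of the genes in this paragraph lay between 0.0996 (ABCA1) and 0.206 (ADAMTS6). Of these genes, HAS2, MTSS1, TFAP2C and SYT11 each carry 1 miR-200a seed site in the 3' UTR.

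**Figure D1:**
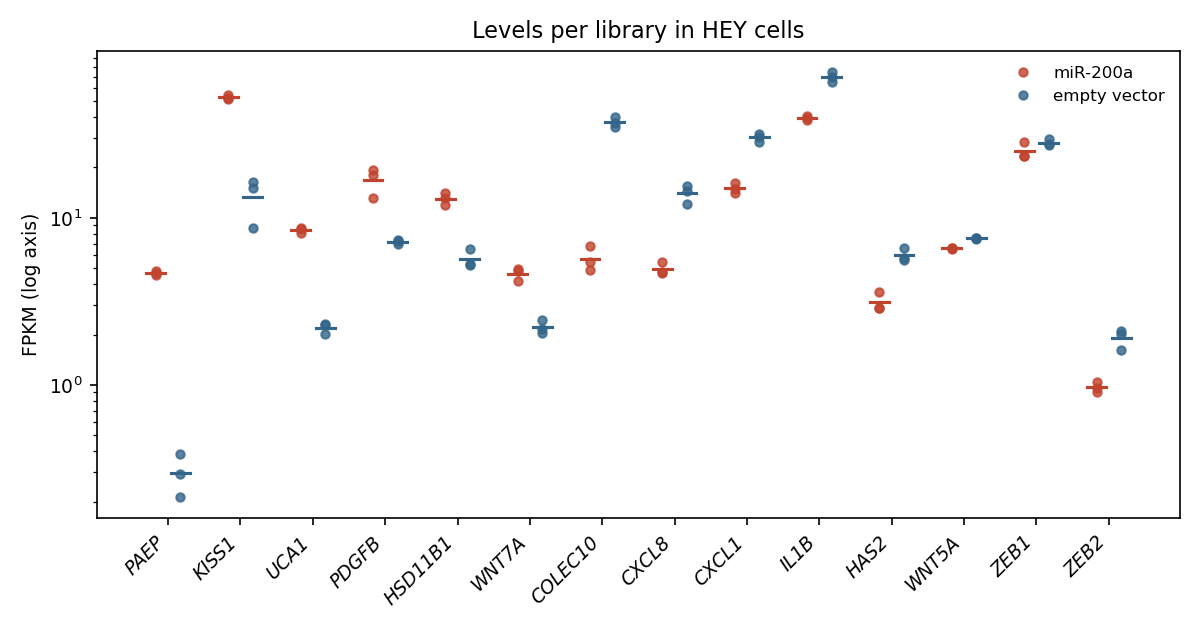
FPKM of 14 genes in each library on a log axis (red, miR-200a; blue, empty vector; bars, group means; n = 3 each). PAEP, KISS1, UCA1, PDGFB, HSD11B1 and WNT7A lie higher in all miR-200a libraries, and COLEC10, CXCL8, CXCL1, IL1B and HAS2 lower, while the libraries of the groups overlap for ZEB1.

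In all, 12231 genes were tested with limma, of which 35 rose and 14 fell at an adjusted p under 0.05, with 13 and 2 of them at least 2-fold on the log2(FPKM + 1) scale. Unadjusted p-values under 0.05 were found for 1623 genes, and in 2321 genes (19.0%) the groups did not overlap, where chance gives 10%. The number of calls varied with the libraries used. It was 8 without miR-200a 1, 225 without miR-200a 2, 9 without miR-200a 3, 9 without vector 1, 9 without vector 2 and 8 without vector 3, and 6 genes (PAEP, XIST, COLEC10, UCA1, C6orf141 and CXCL8) were called in each of these fits. Of the fits added after seeing the data, the correction for GC content and length called 144 higher and 92 lower genes, including all 49, and voom on recovered reads 148 higher and 51 lower. Fewer were called by the correction with the replicate block (37 genes) and without miR-200a 1 and 3 (2 genes), where 1 miR-200a library was left and was assumed to vary like the vector libraries.

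The 3 genes of the axis in the title moved little or were near the limit of detection. WNT5A, a ligand of noncanonical Wnt signalling (ENSG00000114251, chromosome 3, 55465715 to 55490539), stood at 6.57 ± 0.0848 FPKM with miR-200a and 7.56 ± 0.0649 with the vector (SD, n = 3 each). Its log2 difference was -0.18 (SE 0.062), lower in 3 of 3 libraries, with a limma adjusted p of 0.322 and an exact permutation p of 0.1, the smallest that 10 splits allow. IL6, the gene of interleukin-6 (ENSG00000136244, chromosome 7, 22725884 to 22732002), had 4 to 7 reads per miR-200a library and 4 to 9 per vector library, and no difference was detectable at this depth (0.157 ± 0.0463 against 0.182 ± 0.0620 FPKM, n = 3 each, exact permutation p = 0.6). VTCN1, which encodes B7-H4 (ENSG00000134258, chromosome 1, 117143587 to 117210960), was listed at 0 in all 6 libraries.

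Among the classical targets and markers of the miR-200 family, none passed the test. ZEB2, a repressor of epithelial genes with 4 seed sites in its 3' UTR, stood at 0.971 ± 0.0667 against 1.91 ± 0.266 FPKM with no overlap between the groups (n = 3 each, limma adjusted p = 0.112, exact permutation p = 0.1). With voom on recovered reads, a fit added after seeing the data, its adjusted p was 0.00291. ZEB1, with 3 seed sites, stood at 25.1 ± 2.90 against 28.2 ± 1.12 FPKM (n = 3 each, limma adjusted p = 0.464, exact permutation p = 0.3). CDH1, the gene of E-cadherin (ENSG00000039068), was listed at 0 in all 6 libraries. VIM, the gene of vimentin, stood at 829 against 879 FPKM (limma adjusted p = 0.647), and CTNNB1, the gene of beta-catenin, at 48.5 against 51.0 (limma adjusted p = 0.617).

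NF-kB cytokines and targets were lower as a group with miR-200a. Of 26 members, 18 were tested, and CXCL8, CXCL1 and IL1B fell over all genes tested. Adjusted over the list alone, 8 fell and 0 rose, the other 5 being CXCL2 (1.52 against 2.36 FPKM), CXCL3 (0.894 against 1.69), NFKBIA (11.5 against 14.3), BIRC3 (2.54 against 3.83) and ICAM1 (3.89 against 5.87). The median log2 change was -0.18, and camera gave an adjusted p of 1.55e-05, between 1.26e-07 and 0.0252 with each library left out. With an estimated correlation the adjusted p was 0.128. Interleukin-1 alpha differed less, with IL1A at 51.2 against 58.8 FPKM (limma adjusted p = 0.412). CXCL1, CXCL2 and CXCL3 are close copies of each other, and as the treatment of reads that match several genes is not given in the sources used here, their separate levels are uncertain.

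**Figure D2:**
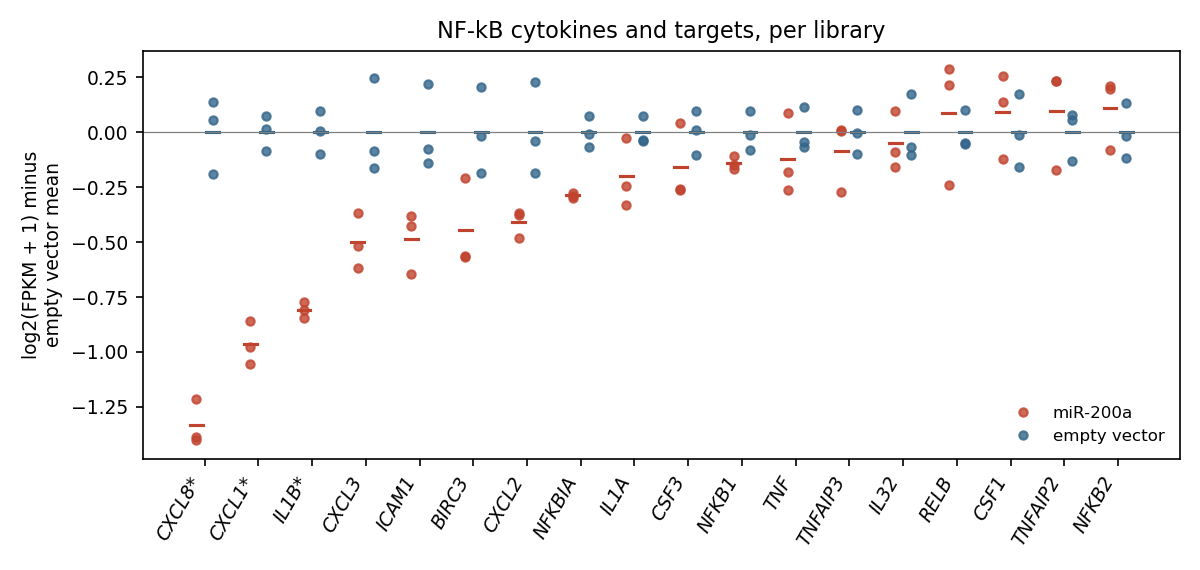
Level of the 18 tested members of the NF-kB list in each library, as log2(FPKM + 1) minus the mean of the vector libraries (red, miR-200a; blue, empty vector; bars, group means; n = 3 each; asterisk, limma adjusted p under 0.05 over all tested genes). CXCL8, CXCL1 and IL1B carry the asterisk and have the lowest miR-200a means, at -1.33, -0.96 and -0.81.

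Reported targets of miR-200a and miR-141, which share the seed, were lower as a group (19 of 23 tested, median log2 change -0.10, camera adjusted p = 0.0143). With an estimated correlation the adjusted p was 0.34. No member passed over all genes tested, and 1, ZEB2, was lower adjusted over the list alone. Other members included ERBIN at 25.1 against 30.1 FPKM, KLF11 at 1.18 against 1.59 and E2F3 at 8.72 against 10.1.

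Epithelial and mesenchymal genes both leaned towards higher levels. Of 30 epithelial genes only 8 were expressed enough to be tested, none of which passed over all genes tested, and 2 were higher adjusted over the list alone, the desmosome gene DSP (18.5 against 12.1 FPKM) and the keratin gene KRT7 (183 against 132). Their median log2 change was 0.24 with a camera adjusted p of 0.0143, or an adjusted p of 0.34 with an estimated correlation and 0.0908 after the GC and length correction. Without miR-200a 2 the median was 0.377, and after the GC and length correction it was 0.112. The keratin gene KRT19 was the only tested member with a negative change, at 1.061 against 1.745 FPKM (log2 change -0.413). After the correction AP1M2 (-0.038) and PKP3 (-0.064) were negative as well, and the others stayed above 0. Members below the filter also went both ways, with EPCAM at 0.131 against 0.263 FPKM and CLDN7 at 0.716 against 0.240. Of 30 mesenchymal genes 19 were tested and none passed over all genes tested. Adjusted over the list alone, 3 were higher, the gelatinase gene MMP2 (6.79 against 3.12 FPKM), TGFBI (78.0 against 57.5) and TWIST2 (32.8 against 23.9), and 1, ZEB2, was lower. The mesenchymal median was 0.13 with a camera adjusted p of 0.0433, or an adjusted p of 0.587 with an estimated correlation, 0.0702 without miR-200a 3, 0.077 without vector 2 and 0.0634 without vector 3.

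Among Wnt ligands and receptors (21 of 38 tested), WNT7A and DKK1 rose. DKK1, a secreted Wnt antagonist, stood at 33.1 ± 2.14 against 20.7 ± 0.969 FPKM (n = 3 each, limma adjusted p = 0.026, up to 0.137 with 1 library left out). Adjusted over the list alone, 4 were higher, the other two being FZD7 (5.01 against 3.43 FPKM) and WNT7B (4.67 against 2.81), and 0 were lower. The list did not move as a whole (camera adjusted p = 0.442, adjusted p = 0.844 with an estimated correlation), its median log2 change being -0.002 and its mean 0.095, so the signs differed. Of 18 Wnt/beta-catenin targets 8 were tested, DKK1 rose over all genes tested, and DKK1 and LGR5 (1.69 against 0.803 FPKM) were higher adjusted over the list alone. That list had a median of 0.11 and a camera adjusted p of 0.0143, or an adjusted p of 0.464 with an estimated correlation and 0.0624 without vector 2. Its median was 0.209 without miR-200a 2 and 0.172 without vector 1. The TGF-beta response list (15 of 19 tested) had a median of 0.14 and a camera adjusted p of 0.0143, or an adjusted p of 0.464 with an estimated correlation, 0.077 without vector 2 and 0.0548 after the GC and length correction. Its median ranged from 0.077 without miR-200a 3 to 0.236 without miR-200a 2, and was 0.081 without miR-200a 1 or vector 2. None of its members passed over all genes tested, and 2 were higher adjusted over the list alone, TGFBI and CCN2, listed as CTGF (419 against 310 FPKM).

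Genes of the interleukin-6 and B7 pathways did not move as groups. None of 17 tested members of the IL-6/STAT3 pathway passed, over all genes or adjusted over the list alone (camera adjusted p = 0.831), with the receptor gene IL6ST at 26.5 against 32.4 FPKM. In the B7 family and immune ligands, 12 of 22 were tested and NCR3LG1, the ligand of an activating receptor of natural killer cells, was lower adjusted over the list alone (2.37 against 3.54 FPKM, camera adjusted p of the list = 0.585). CD274, the gene of PD-L1, stood at 5.43 against 5.03 FPKM and CD276 at 9.48 against 6.91. HLA class I presentation had 11 tested members, none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.585).

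Proteases, integrins and invasion genes (22 of 32 tested) had 0 members past the threshold over all genes, and 5 higher and 2 lower adjusted over the list alone, among them the urokinase gene PLAU (344 against 262 FPKM) and TIMP3 (1.48 against 0.556), with a camera adjusted p of 0.0812. YAP/TEAD targets had 16 tested members, 1 of them higher adjusted over the list alone (camera adjusted p = 0.0932), and ovarian lineage 6, with SOX17 (3.77 against 1.93 FPKM) higher adjusted over the list alone and PAX8 at 37.6 against 31.5 (camera adjusted p = 0.0715). NRF2 targets had 11 tested members, with NQO1 (30.7 against 37.5 FPKM) lower adjusted over the list alone (camera adjusted p = 0.0993), and hypoxia and glycolysis 16, with the glucose transporter gene SLC2A3 (12.6 against 16.3 FPKM) lower adjusted over the list alone (camera adjusted p = 0.893).

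No member passed, over all genes or adjusted over the list alone, among 16 tested interferon response genes (camera adjusted p = 0.893), 26 proliferation genes (0.893), 13 p53 targets (0.954), 16 genes of the unfolded protein and integrated stress responses (0.988), 17 cholesterol synthesis genes (0.943), 13 mitochondrial transcripts (0.0586) and 12 reference genes (0.832). The p53 list had a median of 0.039 and a mean of -0.012, and the stress list a median of 0.024 against a downward test. The cholesterol synthesis list had a median of -0.012 and a mean of 0.017, so in each of these lists the signs differed. The proliferation gene AURKA stood at 53.7 against 63.0 FPKM and GAPDH at 1701 in both groups. Of 16 markers of other cell types 1 reached the filter, the endothelial cadherin gene CDH5 at 47.0 against 38.0 FPKM (limma adjusted p = 0.367), so the list was not tested as a group. In all, 6 of the lists passed camera with the preset correlation and 0 with an estimated correlation. Of these lists, fry, which tests whether members move one way on balance, gave adjusted p-values of 0.00344 for NF-kB, 0.0151 for the reported targets and 0.0345 for epithelial genes, and of 0.213 for mesenchymal genes, 0.0911 for Wnt/beta-catenin targets and 0.114 for the TGF-beta response.

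Transcripts with a miR-200a seed site in the 3' UTR were slightly lower with miR-200a. The 2261 tested genes with CAGTGTT had a median log2 change 0.06 below that of the 7948 genes without it (difference -0.0634, camera p = 0.000211, p = 0.132 with an estimated correlation). For the 604 genes with the 8-mer CAGTGTTA the difference was -0.0745 (camera p = 8.76e-07, p = 0.174 with an estimated correlation), and for CAGTATT, the site of the relatives miR-200b and miR-200c, it was -0.0672 (camera p = 0.000104, p = 0.262 with an estimated correlation). After the GC and length correction the differences were -0.0141 for the seed site (camera p = 0.147, p = 0.00335 with an estimated correlation), -0.0281 for the 8-mer (p = 0.0122 and 0.0152) and 0.0021 for CAGTATT (p = 0.776 and 0.496). With the replicate block as well, the camera p of the seed site with an estimated correlation was 0.0543. Libraries differed in their trend with GC content. The correlation across genes, which are not independent replicates, between a library's deviation and GC content was 0.524, -0.37 and 0.50 in miR-200a libraries 1 to 3 and -0.142, -0.437 and -0.114 in vector libraries 1 to 3.

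Sites were more frequent among genes that fell than among other genes. A site was present in 6 of 12 scanned genes that fell against 22.1% of the others (odds ratio 3.52, 95% interval 0.940 to 13.2, Fisher's exact p = 0.0313). After the GC and length correction it was present in 29 of 82 genes that fell against 22.04% of the others (odds ratio 1.94, interval 1.18 to 3.11, Fisher's exact p = 0.00696). With voom, which was not corrected for GC content, it was present in 23 of 45 against 21.9% (odds ratio 3.73, interval 1.98 to 7.03, Fisher's exact p = 1.7e-05). These odds ratios stand against a median of 1.16 over the reordered 7-mers after the correction (highest 5.00) and of 1.47 with voom (highest 5.68), and 3' UTRs were longer in genes that fell with voom (median 1993 bases against 1404 in the others). Of the genes that rose, 3 of 28 had a site (Fisher's exact p = 0.175). Median log2 changes after the correction were -0.0082 for genes without a site, -0.0203 for 1 site, -0.0361 for 2 sites and -0.0336 for 3 or more.

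**Figure D3:**
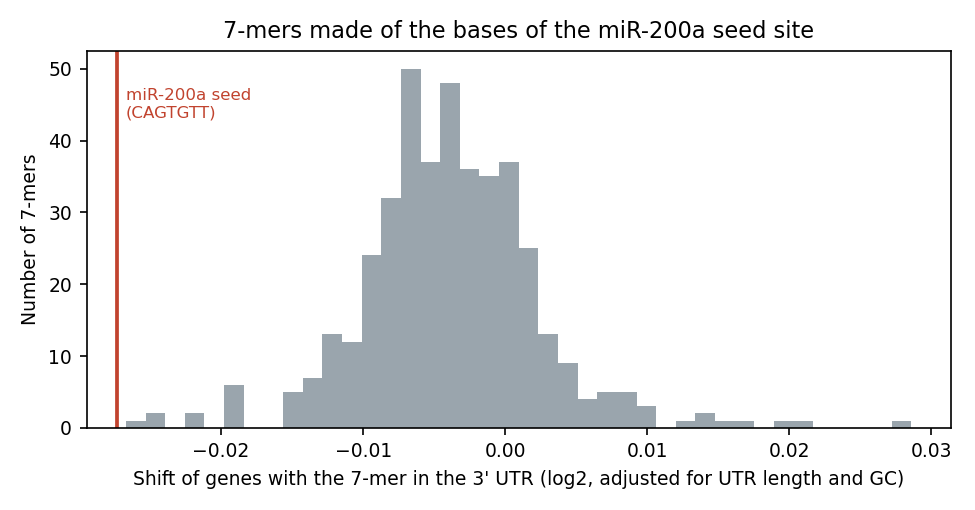
Histogram of the difference in log2 change between genes with and without each of 420 orderings of the bases of CAGTGTT, with 3' UTR length and GC content in the model and after the GC and length correction of the libraries. The vertical axis counts 7-mers, and the red line marks the miR-200a site at -0.0273, the lowest of the 420, with the next lowest at -0.0267.

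Genes in 7 stretches of the genome, each a run of 2 or more neighbouring blocks beyond the limit, were shifted together by 1.09- to 1.18-fold. This comparison was chosen after seeing the data. On chromosome 2 from 215.9 to 238.2 Mb (MREG to ILKAP), 75 genes had a median log2 change of 0.24, 1.18-fold higher, with 96% of them above 0. Chromosome 16 parted into a higher segment up to 31.1 Mb (POLR3K to VKORC1, 200 genes, median 0.15) and a lower one from 53.1 to 75.8 Mb (CHD9 to TERF2IP, 125 genes, median -0.15). On chromosome 15, the stretches from 59.1 to 74.9 Mb and from 79.3 to 96.3 Mb were higher (medians 0.17 and 0.15), and 91.9% of the 284 genes of the chromosome lay above 0. The stretch of chromosome 20 from 50.9 to 64.1 Mb was lower (75 genes, median -0.13) and that of chromosome 22 from 41.5 to 50.2 Mb higher (50 genes, median 0.13). Smaller shifts were not limited to these stretches. Chromosomes 7 and 14 had no block beyond the limit, yet 71.67% of 420 genes of chromosome 7 and 22.15% of 316 genes of chromosome 14 lay above 0.

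These values were taken after the GC and length correction, from blocks of 25 consecutive genes. Of 384 blocks, 20 were higher and 8 lower than the largest block median in any of the other 9 splits of the libraries, 0.117. Blocks beyond the limit with no such neighbour were not counted as stretches. They lay on chromosome 15 from 22495570 to 34338060 (median 0.2095) and on chromosome 22 from 36510850 to 38701556 (0.1322). Before the correction no block of the real split passed this rule, as its largest block median was 0.305 against 0.385 in another split. The medians of the chromosome 2 stretch were 0.104, 0.125 and 0.117 in miR-200a libraries 1 to 3 and -0.107, -0.117 and -0.117 in vector libraries 1 to 3. The stretches held 650 genes, 6.6% of those used, and 48 of the 216 genes called among them after the correction (22.2%). Stretches and calls came from the same values and comparison, so a larger share of calls follows from how the stretches were chosen. Genes named above that lie in a higher stretch are FBLN1, WNT7B and CD276, and in a lower one TFAP2C, AURKA, NQO1 and CDH1. MMP2 and CDH5 lie in a lower stretch too, although their own values were higher with miR-200a. TWIST2 starts at 238848032 on chromosome 2, past the last whole block, and was in no block. That last block had a median of 0.2731 and TWIST2 a corrected log2 change of 0.362. Whether TWIST2 shares the shift of the stretch beside it was not tested.

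**Figure D4:**
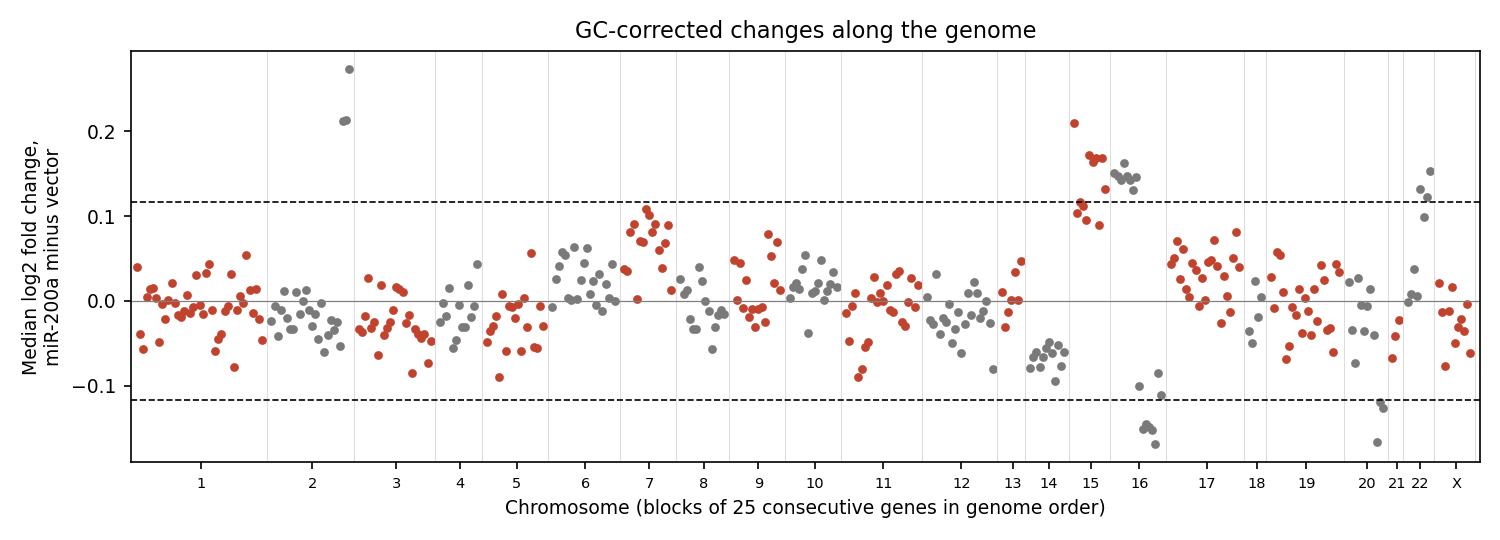
Median log2 change (miR-200a minus vector, GC and length corrected) of blocks of 25 consecutive genes along the chromosomes, with colours alternating by chromosome and dashed lines at the limit of 0.117 on either side of 0. The blocks beyond the limits include the end of chromosome 2, several blocks of chromosome 15 and both parts of chromosome 16.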

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

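The voom fit, the GC and length correction (alone or with the replicate block), the fit without miR-200a 1 and 3 and the estimated correlation of seed-site genes were chosen only after the results were seen. The fit without miR-200a 1 and 3 compares 1 library with 3, with the spread taken from the vector libraries, so its p-values and counts say nothing on stability. The planned count-model alternative was not run because the values are FPKM, and voom on recovered reads took its place. Depth limits IL6 (4 to 9 reads per library) and MIR200A (20 reads). In simulated libraries with a GC trend and the same spread for all genes, 47.8% of 1.5-fold changes were found (12255 genes tested), which may be too high for the real genes. All 49 called genes kept their direction in each refit that tested all of them, and so did the 48 that voom tested (MIR200A had too few reads). Where the groups do not overlap, leaving out a library cannot turn the direction, so this says little on stability. The cause of each change below was not tested, except that some fits used fewer libraries or another number of genes by construction.

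Against 35 higher genes, counts were 4 without a filter (31124 genes tested), 22 at a mean of at least 5 FPKM, 68 among protein-coding genes, 148 with voom, 144 GC-corrected, 23 GC-corrected with the replicate block, 1 without miR-200a 1 and 3, and 4 to 160 with 1 library left out. Against 14 lower genes they were 1 without a filter, 9 scaled to TPM, 28 among protein-coding genes, 51 with voom, 92 GC-corrected, 1 without miR-200a 1 and 3, and 2 to 65 with 1 library left out. The share of calls that were higher was 71.4%, and 61% after the GC correction. At 2-fold, 13 higher genes became 4 without a filter, 6 at 5 FPKM, 8 among protein-coding genes, 85 with voom, 7 GC-corrected with the block, 1 without miR-200a 1 and 3, and 4 to 16 with 1 library left out. The 2 lower ones became 5 and 4 with pseudocounts of 0.1 and 0.5, 1 without a filter, 4 with TPM, 6 with the replicate block, 10 with voom, 4 GC-corrected, 1 without miR-200a 1 and 3, and 2 to 6 with 1 library left out. Among the fits with 1 library left out, the highest of these counts came without miR-200a 2.

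Replicate numbers did not pair the samples: correlations of same-numbered libraries were 0.143, 0.366 and -0.006, and not every library correlated best with its own number. With the replicate block 69 genes were called, 43 of them shared with the 49, and 9 lists passed, among them proteases, integrins and invasion (adjusted p = 0.0454), ovarian lineage (0.025) and mitochondrial transcripts (0.0366), which did not pass without it.

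The seed-site shift of -0.0634 was -0.0141 GC-corrected (camera p = 0.147) and -0.0141 with the block as well (camera p = 0.186, or p = 0.0543 with an estimated correlation). The shift was -0.0086 without miR-200a 1 and 3, and -0.0634 with an estimated correlation (camera p = 0.132). It ranged from -0.0941 to -0.0491 with 1 library left out. Of gene lists, 6 passed, against 2 at a mean of at least 5 FPKM, 2 without miR-200a 1 and 3, 0 with an estimated correlation and 3 to 9 with 1 library left out (3 without vector 2). WNT5A had a log2 change of -0.20 to -0.11 and an adjusted p of 0.103 to 0.989 over all alternatives.

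Genes with no call turned direction in few fits, and the cause was not tested. Without miR-200a 1 and 3 the log2 changes were 0.016 for ZEB1, 0.041 for VIM, -0.004 for CDKN1B, -0.124 for MSLN, -0.017 for FOXL2, 0.007 for MT-CO3, -0.039 for ACTB, 0.038 for HPRT1 and 0.093 for YWHAZ. GC-corrected, with or without the block, they were -0.074 for CDKN1C and -0.025 for MVD. With 1 library left out they ranged from -0.009 to 0.172 for CDKN1C and from -0.069 to 0.006 for IL6.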

Other observations

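Tests chosen only after the result was seen are the GC correction of the other split and of the seed-site shift, the MIR200A reads as a test of swapped labels, the model with 3' UTR composition, the spread of neighbouring genes after the correction, and the counts over splits for corrected calls and for neighbouring genes.

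ID1, an inhibitor of differentiation, rose from 29.1 to 49.0 FPKM (n = 3 each, limma adjusted p = 0.026), and SMAD3, a transducer of TGF-beta signals, from 17.7 to 26.8 (limma adjusted p = 0.0345). Both lie outside the naming rule and were chosen after their values were seen, and SMAD3 lies in the higher stretch of chromosome 15. Of the TGF-beta response list fixed in advance, 0 of 15 tested members passed with limma over all genes tested. After the GC and length correction, and likewise with voom, 2 members were higher and 0 lower. ID1 and SMAD3 are not on that list and were picked by their values, so they stand for no theme.

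Neighbouring genes moved together between the groups, and a candidate explanation, as a hypothesis, is a different gene copy number in the miR-200a and the vector cells. Fold changes of genes 5 to 20 Mb apart correlated at r = 0.1143 across gene pairs, which are not independent, against 0.0777 in the highest other split. The stretches came from the same fold changes, so this correlation partly restates the pattern. It cannot tell copy number from other causes that act over long distances. GC content and length bias is argued against as the whole cause by the SD of block medians after the correction, 0.0592 against 0.0378 in the highest other split, although before the correction other splits were as spread (0.0999 against 0.118), and an effect of miR-200a through its seed by the SD over genes without a site, 0.0569 against 0.0358. Counting the real split itself, 1 of the 10 splits of the libraries was as spread, and the splits are too few for a share under 0.05. DNA was not analysed here, and changes of chromatin over long stretches were not tested, so both stay open. After the correction, the shifts of their stretches (0.131 and -0.127) were a small part of the log2 changes of FBLN1 (0.705) and TFAP2C (-0.722). For some named genes they were most of the change, at 0.165 against 0.231 for CD276, -0.153 against -0.242 for NQO1 and -0.127 against -0.197 for AURKA. WNT7B lay between (0.131 against 0.356), and MMP2 and CDH5 moved against their stretch.

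Seed-site genes were lower before correction, and the GC trend of the libraries may account for most of it, since the shift of -0.0634 became -0.0141 after the correction (camera p = 0.147, or p = 0.00335 with an estimated correlation, and 0.0543 if the replicate block is added to the latter). With length and GC content of the 3' UTR in the model, the shift was -0.0273. It was the lowest of 420 orderings of the same bases, though close to the next at -0.0267. Some splits that mix the groups ranked the site high too, at 6 (-0.0095), 9 (-0.0143) and 11 (-0.0106) of 420. The split of miR-200a 1, miR-200a 3 and vector 1 ranked it 16 (-0.0225), while others ranked it as far down as 29 (-0.0013). The rank therefore cannot decide whether length and GC content of the 3' UTR are the whole cause of what was left. Whether miR-200a lowered transcripts with its site cannot be told apart from other sequence effects, since by odds ratio among corrected genes that fell the site ranked 47 of 420 with a confidence interval (1.18 to 3.11) that holds the 2.34 of rank 21. Among voom calls it ranked 9, but the voom fit was not corrected for GC content. With voom, genes with CAGTATT were shifted by -0.0854 and genes with the miR-200a site by -0.079, so the voom rank may carry the GC trend. Counting the real split itself, the uncorrected shift was as large in 2 of the 10 splits, with -0.0688 in the highest other split. After the correction other splits gave -0.0165 and 0.0147 beside the real -0.0141, so the corrected shift does not stand out among them. The splits are too few for a share under 0.05.

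The split of miR-200a 1, miR-200a 3 and vector 1 against the other 3 libraries called 838 genes, many more than the 49 of the real split, which points to a structure of the samples beside the groups. After the GC and length correction it called 80 and the real split 236, so a GC or length bias between libraries may account for most of it. Swapped labels of miR-200a 2 and vector 1 are argued against by the 4 MIR200A reads in miR-200a 2 and 0 in vector 1. Counting the real split itself, as many genes were called in 2 of the 10 splits before the correction (highest other 838) and in 1 after it (highest other 80). Counted in the same way, as many 2-fold calls were found in 1 (15 against 9) and as many lists in 1 (6 against 2). These splits are too few for a share under 0.05.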
